A study of Mus musculus with 23 samples.

How the data were processed

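Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 3T3-L1 cells. This established mouse line consists of preadipocytes that can be turned into fat cells. Per the labels, cells received 50 nM of a non-targeting siRNA, called scramble here, or of siRNA against Kdm5c on day -3. Nuclei were taken 24, 48 or 72 hours later, on days -2, -1 and 0. The labels put the 23 libraries in 6 groups of 4, except that Kdm5c siRNA on day 0 has 3, numbered 1, 2 and 4. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

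The authors deposited, for each day, a table of whole-number counts of reads per peak, and these raw counts entered the tests. The authors also deposited, for each day, a table of normalised signal for the peaks they gave a gene name. Each library's signal equalled its raw count divided by 1 constant, within a tolerance of 1e-08, so this table added no information beyond the gene names. Per the submitters' processing notes, cutadapt 2.3, Bowtie2 2.2.9, MACS2 2.1.1, HTSeq 0.9.1 and DESeq2 1.24.0 were used on the GRCm38 build. The role and settings of each tool, the pooling of libraries for peak calling, and the treatment of duplicate reads, mitochondrial reads and transposase offset are not given in the sources used here. Reads that map equally well to several places could be counted differently depending on those settings.

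Each day had its own peak set, with 84019, 31970 and 37054 peaks on days -2, -1 and 0. The authors gave a gene to 12268, 9692 and 10134 of these. Of those peaks, 88.5%, 90.8% and 90.8% lay within 1 kb of an end of a coding gene, against 5.83%, 8.10% and 8.02% of the others. Because no strand or transcription start was at hand, peaks with an authors' gene served as the promoter class. Other peaks were placed with a table of gene spans of GRCm38.p6, as within 1 kb of an end of a gene, inside a gene, or within 10 kb of it. That table does not separate exons from introns. It held 98.3%, 98.9% and 98.9% of the gene names used by the authors. Coordinates are printed as deposited, and whether their starts count from 0 or 1 is not given in the sources used here.

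Counts summed over peaks ranged from 4474964 to 14913397 per library. Mitochondrial peaks held 56.4% to 93.2% of them, which left 781309 to 3345583 nuclear counts. The median tested peak had 22.4, 26.8 and 26.1 counts per library on days -2, -1 and 0.

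Each day was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on that day's libraries alone, with TMM factors, filterByExpr and no covariate. Benjamini-Hochberg adjusted p-values under 0.05 were called. TMM sets the bulk of nuclear peaks to no average change, so every fold change is relative to that bulk. Scaling by total counts alone instead moves the median peak by 0.44, 0.38 and 0.56 on the log2 scale on the 3 days, since mitochondrial reads dominate the totals. Normalised counts are raw counts divided by relative effective library size. Standard errors were derived from the F statistic. That test pools information on spread over peaks, so such an error may be smaller than the scatter of the libraries at that peak. DESeq2 1.42.0 was the second tool.

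Differences of the siRNA effect between days were tested as interactions in 1 fit over all libraries. Peaks were matched 1 to 1 by a reciprocal overlap of 50%, found with bedtools 2.31.1. This gave 13675 peaks on all 3 days, of which 13670 were tested. Library shares were compared by two-sided exact permutation tests in Python 3.11.15 with scipy 1.17.1, and adjusted over the 10 measures of a day. Correlations across libraries used 100000 permutations.

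Of the 18 gene lists, those with a measured member were tested with camera in limma 3.58.1, with a preset correlation of 0.01 on voom values. Camera with an estimated correlation and fry stood beside it. Fry's directional p tests whether genes of a list move, on balance, one way, and its mixed p whether they change in either direction. Each gene was represented by its authors' gene peak with the highest mean count, in place of the peak nearest to a transcription start.

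The groups, designs, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. Added later were leaving out libraries for the list tests, for the correlation of effects between days and for the mitochondrial share, other scaling, matching and block for that correlation, and the tests that the other texts name as added. That rule takes, per day, called peaks at a named gene whose arms do not overlap, up to 10 in each direction. It leaves out symbols that are only clone or model names, and peaks below the median abundance. Where none passes, it takes the 5 with the smallest p, and it adds every called list member and the Kdm5c peaks. Other genes, among them the list members, none of which was called, were chosen after their values were seen. Of list members the report gives those with an unadjusted edgeR p under 0.05, with Pparg and Cebpa. The value of 1 peak is not reported here.

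The tests were tried on simulated data, with 200 peaks changed among those tested on each day. The spread came from the fit and was not set for each single peak, and libraries were drawn independently, so recovery in the real data may be lower. Among 2-fold changes, 34%, 42% and 39.5% were recovered on days -2, -1 and 0, and among 3-fold changes 67%, 87.5% and 72%. At 1.5-fold the shares were 4.5%, 8.5% and 8%, and at 1.25-fold they were 0%. In simulated sets of 20 lists of 25 genes, camera called all 5 lists moved by 1.25-fold on each day, and 1, 2 and 1 of the lists left unmoved. There peaks were drawn independently of each other, and all 25 genes of a moved list rose alike. The real lists, many with fewer measured genes, were not simulated, so this recovery may not hold for them.

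Alternatives were another scaling, another tool, other filters and thresholds, replicate number as a block, another matching of peaks, other list tests, and leaving out each library in turn. GC correction, motif analysis and distances to transcription starts were left out, since no genome sequence or start was used here. Change of scramble libraries over days was planned only for tables with identical peaks, and was not tested here.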

Results

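Open chromatin was profiled in 3T3-L1 mouse preadipocytes during the 3 days before day 0, with and without siRNA against Kdm5c. Kdm5c is an X-linked demethylase of histone H3 that removes methyl groups from lysine 4, a mark of promoters and enhancers. There were 4 libraries per arm and day, and 3 for Kdm5c siRNA on day 0. Total counts in peaks were 4474964 to 12222886 per library on day -2, 9202281 to 14913397 on day -1 and 8166766 to 12814609 on day 0. Nuclear counts were 1816082 to 3345583 on day -2, 781309 to 1446979 on day -1 and 1088968 to 2525925 on day 0. The design asks which regions open or close when Kdm5c is targeted, and whether the answer depends on the day.

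The peak at the Kdm5c gene itself did not differ between arms on any day. It lay within 1 kb of the gene's end at the start of its span, at X:152232661-152233232 on day -2. Normalised counts were 49.3 ± 16.95 (SD, n = 4) with Kdm5c siRNA and 60.8 ± 16.6 (n = 4) with scramble on day -2, a log2 fold change of -0.28 (SE 0.21). On day -1 they were 36.2 ± 16.3 and 33.4 ± 2.17 (n = 4 each), or 0.10 (SE 0.25). On day 0 they were 49.5 ± 5.88 (n = 3) and 44.4 ± 5.95 (n = 4), or 0.14 (SE 0.24). The sign was the opposite on day -2 under total-count scaling, at 0.16, and on day -1 without Kdm5c siRNA replicate 2, at -0.19. The siRNA acts on the mRNA, so this peak does not check the knockdown, and transcript levels were not analysed here.

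On day -2, 24 hours after transfection, 2 regions fell with Kdm5c siRNA, and both carry mitochondrial sequence. A broad peak over the mitochondrial genome, MT:51-6856, named by the authors for the transfer RNA gene mt-Tf, had 2.32e+06 ± 5.89e+05 (SD, n = 4) normalised counts against 3.56e+06 ± 5.26e+05 (n = 4). Its log2 fold change was -0.62 (SE 0.13), an edgeR adjusted p of 0.048. A nuclear peak, 1:24611585-24616148, covers the pseudogenes Gm10222 and Gm10925, the second listed with mt-Atp6 among its synonyms. It fell by 0.68 (SE 0.12, adjusted p = 0.0041), from 4182 ± 742 to 2612 ± 709 normalised counts (n = 4 each). This peak falls outside the rule for named genes, since its arms overlapped, and was chosen after its values were seen. An exact permutation test of its log2 values gave p = 0.0571. Its deviations from group means over the 23 libraries followed the log2 mitochondrial to nuclear ratio, with Pearson's r = 0.950 and Spearman's rho = 0.953 (permutation p = 1e-05 for each, the smallest 100000 permutations can give). The second broad mitochondrial peak, mt-Th, chosen in the same way, had -0.59 (SE 0.13, adjusted p = 0.072).

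Peaks at single genes did not pass on day -2. A peak inside Myo3a, at 2:22588662-22590179, had a log2 fold change of -0.66 (SE 0.15, edgeR adjusted p = 0.40). The promoter-class peak of the linker histone gene Hist1h1c had -0.63 (SE 0.16), with 83.8 ± 4.79 against 130.09 ± 3.66 normalised counts (n = 4 each). Peaks beside C2cd4d and inside the collagen gene Col1a1 had 1.42 (SE 0.36) and 1.20 (SE 0.33). The promoter-class peaks of Mus81, a DNA junction nuclease, of Coro1b, an actin-binding coronin, and of the ubiquitin-conjugating enzyme Ube2q2 had 0.69, 0.71 and 1.17. The promoter-class peak of the splicing regulator Mbnl2 had -0.66. Peaks inside Eps8, Mdfic, Fyco1 and Tbc1d2b had -0.74, -0.84, -0.99 and -1.04. The edgeR adjusted p of Hist1h1c was 0.77, of C2cd4d 0.84 and of the others from Col1a1 on 0.98, and all genes of this paragraph were chosen after their values were seen.

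Of 49455 peaks tested on day -2, edgeR called 2, both lower, and 2291 had an unadjusted p under 0.05, or 4.63%. DESeq2 called 0, with 3008 under 0.05. The mt-Tf peak was not called with RLE size factors or above the median abundance, each with 1 call, nor under total-count scaling, where it had -0.20 and the Gm10222 peak -0.26, uncalled too. The Gm10222 peak was not called without Kdm5c siRNA replicate 1 or scramble replicate 2, at log2 fold changes of -0.55 and -0.57. Without Kdm5c siRNA replicate 3 there were 11 calls, without Kdm5c siRNA replicate 4 there were 4, and without scramble replicate 1 there were 5.

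On day -1, 48 hours after transfection, no region passed the test. The 5 genes with the smallest p were Rsph3a, Katnbl1, Gprc5a, Frmd4a and Stil. The promoter-class peak of Rsph3a, a radial spoke gene of cilia with a close copy, Rsph3b, on the same chromosome, had a log2 fold change of 1.23 (SE 0.28), with 44.7 ± 15.8 normalised counts against 18.4 ± 8.71 (n = 4 each). The peak beside Gprc5a, a retinoic acid-induced receptor gene, had 1.07 (SE 0.25). Katnbl1, related to the microtubule-severing katanins, had -0.75 (SE 0.18), with 52.5 ± 8.14 against 87.7 ± 13.5 (n = 4 each). Stil, needed for centriole duplication, had -0.57 (SE 0.15), and a peak inside Frmd4a had -1.16 (SE 0.29). The edgeR adjusted p was 0.27 for Rsph3a, Katnbl1 and Gprc5a, 0.48 for Frmd4a and 0.54 for Stil.

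Further genes of day -1, chosen after their values were seen, all had an edgeR adjusted p of 0.67 or 0.70. Promoter-class peaks of Deptor, an inhibitor of the mTOR kinase, and of the zinc finger gene Zscan25 had -0.84 and -0.58. Peaks inside St3gal1, Lpcat3 and Ndrg4 had -0.63, -0.59 and -0.64, and those inside Arhgap28 and Tacc2 had 0.55 and 0.80. Of 23304 peaks tested, edgeR called 0 and DESeq2 called 0, with 1253 and 1604 at an unadjusted p under 0.05. The edgeR share was 5.38%. Rsph3a was the 1 call under total-count scaling, at 1.66 (adjusted p = 0.044, against 0.065 to 0.92 in its other alternatives).

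On day 0, 72 hours after transfection, 1 region fell. It is a peak inside Myo3a, an unconventional myosin gene, at 2:22588662-22590179. It had 272 ± 97.7 normalised counts (SD, n = 3) with Kdm5c siRNA and 417 ± 51.7 (n = 4) with scramble, a log2 fold change of -0.64 (SE 0.13, edgeR adjusted p = 0.025). The arms overlapped. This peak too followed the mitochondrial to nuclear ratio over the 23 libraries, with Pearson's r = 0.819 (permutation p = 0.00036) and Spearman's rho = 0.853 (permutation p = 7e-05). A neighbouring peak of the same gene, 2:22587394-22588301, had -0.08 (SE 0.13) on day 0, 0.06 (SE 0.13) on day -1 and -0.69 (SE 0.20, edgeR adjusted p = 0.98) on day -2. There Kdm5c siRNA replicate 2 had 5.28 normalised counts, against 154 to 470 in the other 3 Kdm5c siRNA libraries.

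The next smallest p on day 0 belonged to Cwc22, a spliceosome component. Its peak, inside the gene at 2:77903372-77903600 in a 500 kb window with 4.90 times the median count density, had a log2 fold change of -0.90 (SE 0.20, edgeR adjusted p = 0.050387). S100a10, a partner of annexin A2, had -0.82 (SE 0.19, adjusted p = 0.077) at its promoter-class peak, with 55.9 ± 6.14 (n = 3) against 97.2 ± 13.2 (n = 4). Another peak beside this gene, 3:93555871-93556294, had 0.09 (SE 0.27). The nuclear pore gene Nup107 had -0.64 (SE 0.16, adjusted p = 0.15) at a peak inside the gene, against -0.09 at its promoter-class peak. Both lie in a stretch of chromosome 10 where counts were 12.4 times the genome's median density. The RNA-binding protein gene Hnrnpu had -0.77 (SE 0.20, adjusted p = 0.36). None of these 4 passed. The Gm10222 peak, outside the rule for named genes, had -0.51 (SE 0.12, edgeR adjusted p = 0.086) on day 0 and -0.46 (SE 0.13, adjusted p = 0.70) on day -1. It was called on day 0 without mitochondrial peaks, an alternative added after the data were examined (edgeR adjusted p = 0.019). Among genes chosen after their values were seen, promoter-class peaks of the RNA helicase gene Ddx21 and the coatomer gene Copg1 had 0.88 and -0.74. Peaks inside Styk1, Mepe and Foxk1 had 1.08, -0.75 and -0.70, and those inside Cpm and Slc35e3, in the same stretch as Nup107, both had -0.51. The edgeR adjusted p of the peaks from Ddx21 on was 0.36 to 0.52. The promoter-class peaks of Cpm and Slc35e3 had -0.17 and 0.08.

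Of 28398 peaks tested on day 0, edgeR called 1, and 1701 had an unadjusted p under 0.05, or 5.99%. DESeq2 called 0, with 2083 under 0.05. The Myo3a call was lost without Kdm5c siRNA replicate 4 (log2 fold change -0.37) and without scramble replicate 2, 3 or 4 (-0.67, -0.63 and -0.57), each with 0 calls, and it had -0.13 under total-count scaling. There were 10 calls without Kdm5c siRNA replicate 1 and 5 without scramble replicate 1. Cwc22 was called with RLE size factors, without a low-count filter, and without Kdm5c siRNA replicate 1 or scramble replicate 1, at -0.91, -0.88, -1.09 and -1.09. Nup107 was called without Kdm5c siRNA replicate 1, at -0.80, and S100a10 without scramble replicate 1, at -0.92.

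**Figure D1:**
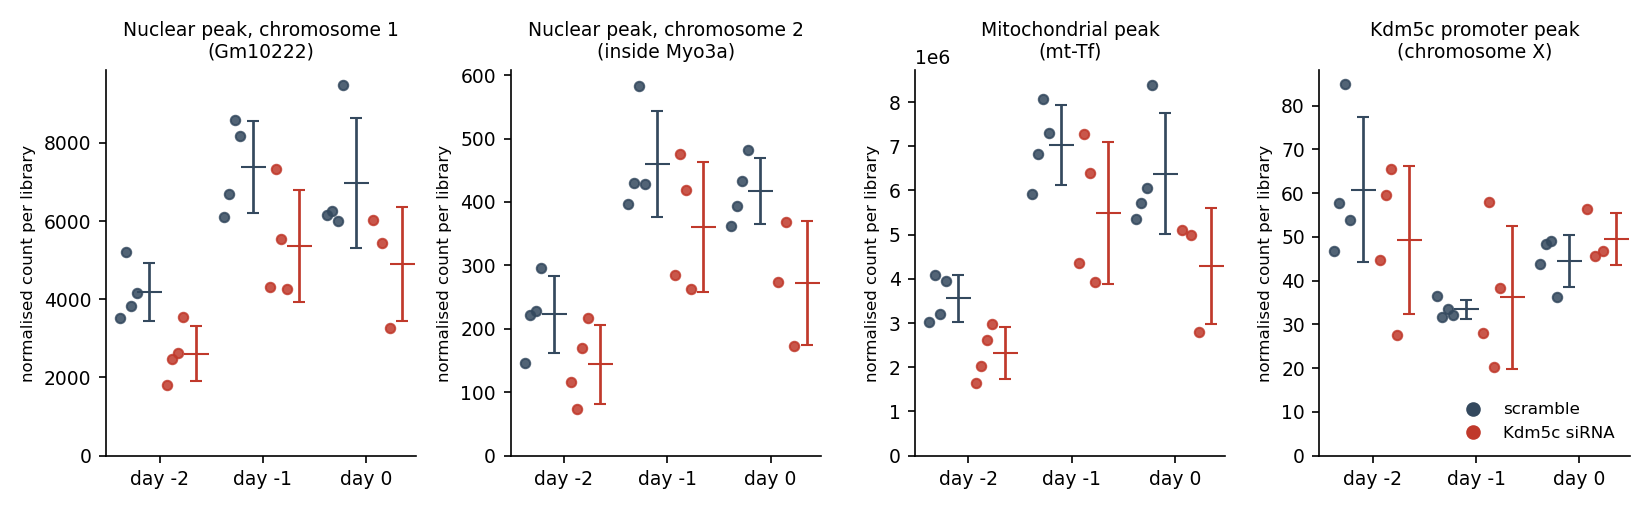
Normalised counts per library (y axes, from 0) at 4 peaks by day (x axes), for scramble (dark) and Kdm5c siRNA (red); points are libraries, and bars show the mean ± SD of each group (n = 4, or 3 for Kdm5c siRNA on day 0). Counts at the Gm10222, Myo3a and mt-Tf peaks have a lower mean with Kdm5c siRNA on each day. Arms overlap at Gm10222, Myo3a and Kdm5c on each day, and at mt-Tf on day -1.

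Of counts in peaks, the share in mitochondrial peaks was lower with Kdm5c siRNA, with arms that did not overlap on days -2 and 0. Reads outside peaks were not counted in this share. It was 63.8% ± 6.26 (SD, n = 4) against 73.5% ± 2.85 (n = 4) on day -2, with an exact permutation p of 0.0286, the smallest the design allows. On day 0 it was 84.1% ± 4.58 (n = 3) against 88.9% ± 1.77 (n = 4), again at an exact p of 0.0286, the smallest possible. On day -1 the values were 90.0% ± 2.49 and 92.3% ± 1.01 (n = 4 each, exact permutation p = 0.20). Adjusted over 10 measures of a day, these exact p-values became 0.143, 0.0952 and 0.643, so no single day passed. This measure was chosen after the data were examined. As a ratio of mitochondrial to nuclear counts, Kdm5c siRNA libraries had 0.636, 0.763 and 0.671 times the scramble level on days -2, -1 and 0. Over the 3 days together the factor was 0.688, a mean log2 difference of -0.54, with an exact permutation p of 0.00041 when arms were permuted within days. The difference did not itself differ between days (exact permutation p = 0.542, 0.873 and 0.688 for the 3 pairs). Without Kdm5c siRNA replicate 4, the day 0 difference of -4.78 percentage points became -2.14. Leaving out any 1 scramble library on day -2 gave an exact p of 0.0571 or 0.0857.

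The share of all counts in promoter-class peaks had a lower mean with Kdm5c siRNA on each day, but no day passed after adjustment. With mitochondrial peaks included, as planned, the shares were 76.5% ± 4.40 and 82.9% ± 1.86 on day -2 (n = 4 each, exact permutation p = 0.0571, adjusted 0.190). They were 94.6% ± 1.34 and 95.8% ± 0.610 on day -1 (exact p = 0.20, adjusted 0.643), and 91.5% ± 2.40 (n = 3) and 93.9% ± 1.00 (n = 4) on day 0 (exact p = 0.0286, adjusted 0.0952). Without Kdm5c siRNA replicate 4 the day 0 difference of -2.47 percentage points became -1.08. The 2 broad mitochondrial peaks carry an authors' gene and so count as promoter class. Among nuclear counts alone, a measure added after the data were examined, the shares were 35.3% and 35.4% on day -2, 45.6% and 45.5% on day -1, and 46.3% and 45.6% on day 0, with exact permutation p-values of 0.914, 0.80 and 0.257. The share in the 1000 most abundant nuclear peaks was 17.4% and 17.3%, 25.5% and 25.8%, and 26.0% and 27.1% (exact p = 0.943, 0.657 and 0.20). Over all counts, the 1000 most abundant peaks held 70.1% and 78.1%, 92.6% and 94.3%, and 88.2% and 91.9% (exact p = 0.0286, 0.171 and 0.0286, adjusted 0.143, 0.643 and 0.0952).

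**Figure D2:**
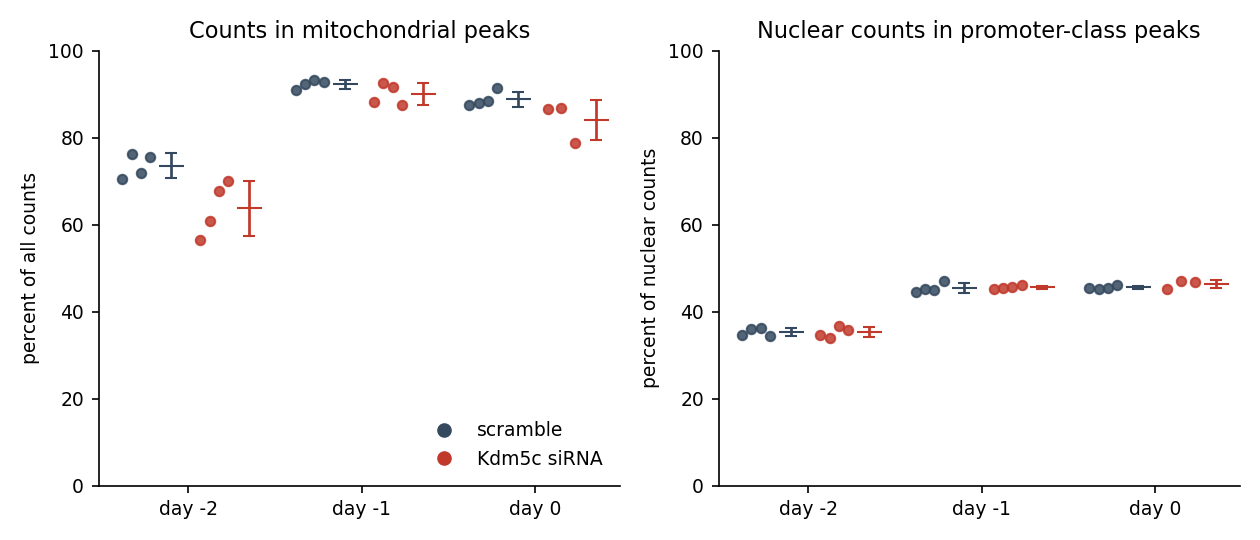
Percent of all counts in mitochondrial peaks (left, y axis 0 to 100) and percent of nuclear counts in promoter-class peaks (right, y axis 0 to 100), by day (x axes), for scramble (dark) and Kdm5c siRNA (red); points are libraries, and bars show the mean ± SD (n = 4, or 3 for Kdm5c siRNA on day 0). Mitochondrial shares of the arms do not overlap on days -2 and 0, and promoter-class shares overlap on each day.

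Nuclear promoter-class and other peaks had median fold changes near 0. TMM sets the bulk of nuclear peaks to no average change, so these medians cannot show a shift shared by all nuclear peaks. They compare the classes only with each other. The medians were 0.028 and -0.014 on the log2 scale on day -2, -0.00069 and -0.0049 on day -1, and -0.014 and -0.0050 on day 0. Of 10836, 8838 and 9555 nuclear promoter-class peaks, edgeR called 0 on each day, and 468, 470 and 459 had an unadjusted p under 0.05. Of these, 324 were higher and 144 lower on day -2, 233 and 237 on day -1, and 185 and 274 on day 0. Among other nuclear peaks at that level, 824 were higher and 996 lower on day -2, 361 and 421 on day -1, and 573 and 667 on day 0, and these splits were not tested. DESeq2 called 0 peaks of any class. Of 38616, 14462 and 18840 other nuclear peaks, 1, 0 and 1 were called. Peaks whose arms did not overlap made up 2.87%, 3.27% and 6.22% of those tested, where chance gives 2.86%, 2.86% and 5.71%.

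No gene list shifted as a whole on any day by camera. The lists held 253, 202 and 216 measured genes on days -2, -1 and 0, of which edgeR and DESeq2 called 0, and 9, 10 and 12 had an unadjusted edgeR p under 0.05 (3.56%, 4.95% and 5.56%). Of 17, 16 and 16 lists tested, 0 had a camera adjusted p under 0.05 and 0 an unadjusted one. The smallest adjusted values were 0.94, 0.97 and 0.74. The same counts of 0 came from an estimated correlation and from fry's directional test.

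Adipogenic transcription factors, which drive fat cell formation, had 20, 17 and 18 measured members, and their median log2 fold changes were 0.01, 0.03 and 0.03. Pparg, the master regulator of fat cells, had 0.03 (SE 0.19), -0.19 (SE 0.30) and -0.26 (SE 0.26) on days -2, -1 and 0. Cebpa had 0.12, 0.20 and 0.18. Cebpb, an early factor, had -0.42 (SE 0.17) and the insulin receptor gene Insr 0.42 (SE 0.21) on day -1, and Zfp467 had 0.65 (SE 0.26) on day 0. Mature adipocyte and lipid genes had medians of 0.08, -0.05 and 0.02 over 16, 14 and 15 members, and Dgat1, which completes triglyceride synthesis, had 0.42 (SE 0.20) on day -1. Preadipocyte and anti-adipogenic genes had medians of 0.03, -0.02 and 0.08 over 14, 11 and 12 members. Foxo1, a repressor of fat cell formation, had 0.56 (SE 0.27) on day -1 and -0.54 (SE 0.26) on day 0, and the Notch target Hes1 had 0.29 (SE 0.15) on day -2. None of these members passed, and they were chosen after their values were seen, as were the list members named in the next 4 paragraphs. No gene of the thermogenic list had a tested peak on any day.

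Proliferation genes had medians of 0.04, 0.03 and -0.09 over 30, 25 and 26 members. On day 0, 10 members were above 0 and 16 below, and 5 had an unadjusted edgeR p under 0.05. Of these Rrm2, a subunit of ribonucleotide reductase, had 0.47 (SE 0.16), the replication helicase gene Mcm2 0.61 (SE 0.25), the mitotic activator Cdc20 0.45 (SE 0.21), thymidylate synthase, Tyms, -0.65 (SE 0.27), and the cyclin gene Ccne1 -0.30 (SE 0.15), none of them called. Fry's mixed test gave this list an adjusted p of 0.0033 on day 0, the 1 list of 16 to pass a test added after the data were examined. The value was 0.21 without Kdm5c siRNA replicate 2 and 0.11 without Kdm5c siRNA replicate 4, in a range of 0.0011 to 0.21 over the libraries left out singly. Without scramble replicate 1 or 2 a second list passed as well, that of adipogenic factors (0.0099) or of preadipocyte genes (0.0060). On days -2 and -1 fry's mixed test called 0 lists, with 0 and 1 at an unadjusted p under 0.05. On day -1, Mcm6, Myc and Ccnd2 had 0.41, 0.61 and 0.54. Cell cycle inhibitors and p53 targets had medians of -0.01, -0.01 and -0.0042 over 15 members on each day.

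Immediate early, AP-1 and YAP target genes had medians of 0.03, 0.08 and 0.10 over 18, 18 and 17 members. Jun, a subunit of the AP-1 factor, had 0.80 (SE 0.24) on day 0, with 64.2 ± 31.2 normalised counts (SD, n = 3) against 35.5 ± 9.98 (n = 4). Its edgeR adjusted p was 0.61 over all peaks and 0.012 adjusted over the list alone. Yap1 had 0.44 (SE 0.21) on the same day, Wwtr1 0.46 (SE 0.20) on day -1 and Fosl1 0.54 (SE 0.21) on day -2. Interferon and innate immune genes, which transfected RNA can induce, had medians of 0.08, 0.04 and 0.06 over 23, 19 and 24 members, with 0.86 (SE 0.30) at the chemokine gene Ccl7 and 0.38 (SE 0.19) at Irf1 on day -2, and 0.44 (SE 0.22) at Tlr3 on day 0. Extracellular matrix genes had medians of 0.02, 0.00034 and -0.0095 over 38, 31 and 36 members. Among them Timp2, an inhibitor of matrix proteases, had -0.63 (SE 0.27) on day 0, and Fbln2 0.34 (SE 0.16) and the promoter-class peak of Col1a1 0.86 (SE 0.38) on day -2.

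Histone H3 lysine 4 methylation enzymes and partners had medians of 0.07, 0.02 and -0.06 over 23, 21 and 21 members. Germline genes, repressed by Kdm5c in other cell types, had medians of 0.12, -0.01 and 0.06 over 8, 1 and 1 members. Imprinted genes had medians of 0.01, 0.37 and -0.12 over 10, 7 and 8 members. Airn, the non-coding RNA that silences Igf2r, had -0.81 (SE 0.28) on day -1, with an edgeR adjusted p of 0.86 over all peaks and 0.038 adjusted over the list alone, and Kcnq1ot1 had 0.48 (SE 0.24) on the same day. Fry's mixed test gave the imprinted list an adjusted p of 0.080 on day -1, and of 0.0044 without scramble replicate 4. For no other list did any member pass when adjusted over the list alone.

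Markers of other lineages were sparse and did not pass either. Osteoblast and chondrocyte genes had medians of 0.06, 0.13 and -0.02 over 7, 4 and 2 members, and myogenic genes -0.05, 0.11 and 0.20 over 6, 2 and 2. Macrophage and blood cell genes had 0.17, 0.04 and 0.29 over 3, 2 and 2, among them Lyz2, in the dense stretch of chromosome 10, and endothelial genes 0.12, 0.0074 and -0.0049 over 5, 1 and 2. Epithelial genes had -0.06 over 2 members on day -2 and no tested member later. Housekeeping genes had 0.06, -0.04 and -0.14 over 16, 15 and 15 members. Dmp1, of the osteoblast list, had -0.57 (SE 0.28), Cldn3, of the epithelial list, 0.69 (SE 0.32) and the housekeeping gene Tubb5 0.47 (SE 0.22) on day -2, and Cd14, of the macrophage list, had 0.64 (SE 0.31) on day 0. Median, mean and camera's direction were not all of 1 sign for several lists. On day -2 these were adipogenic, p53, germline and osteoblast genes. On day -1 they were adipogenic, mature adipocyte, preadipocyte, germline, lysine 4, macrophage and endothelial genes. On day 0 they were preadipocyte, matrix, p53 and endothelial genes.

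**Figure D3:**
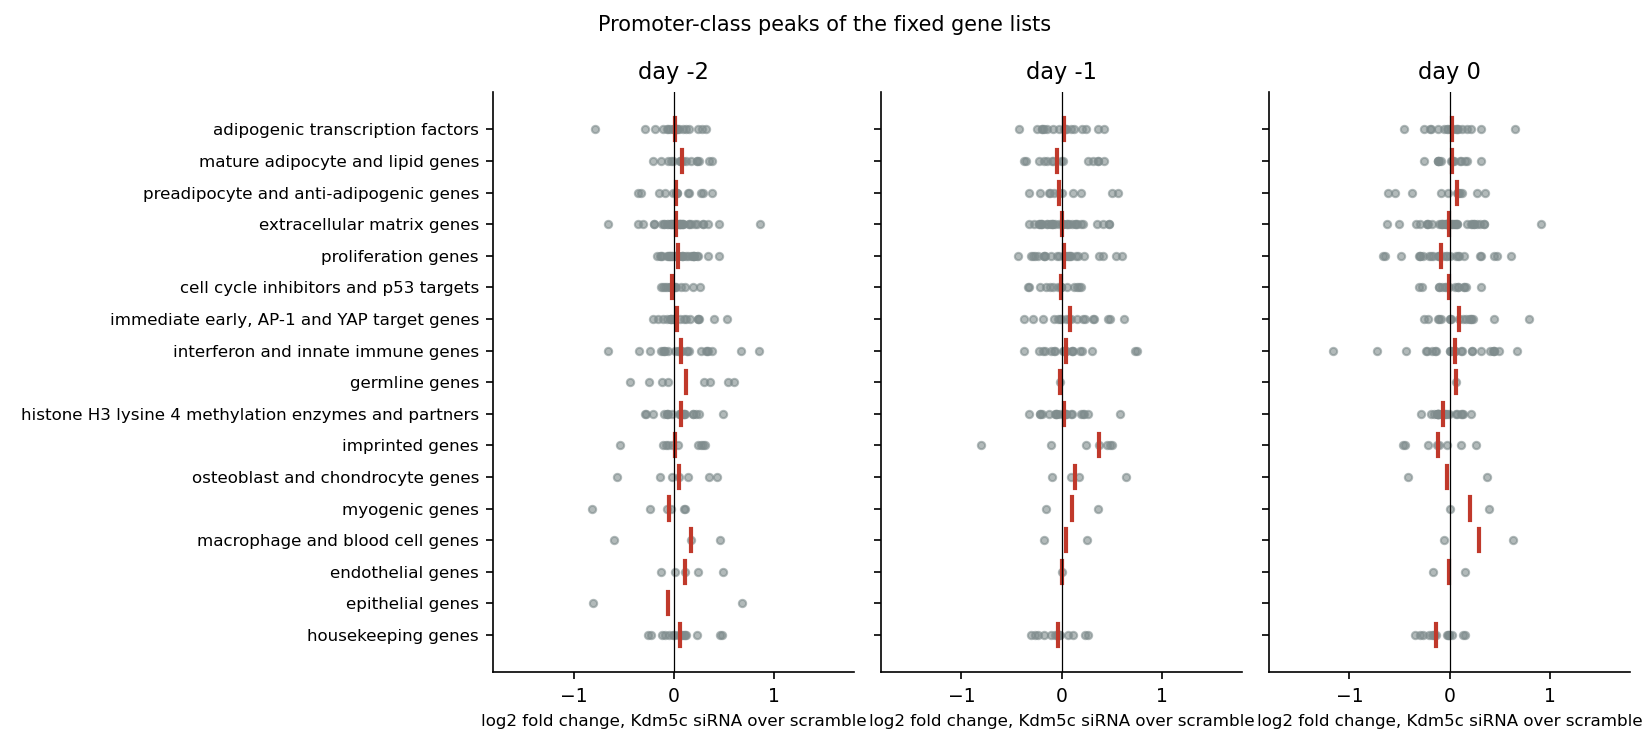
Log2 fold change of Kdm5c siRNA over scramble (x axes) for the promoter-class peak of each measured member of the fixed gene lists (named on the y axis), 1 panel per day; grey points are genes and red ticks the median of each list. Medians lie between -0.14 and 0.37.

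The siRNA effect was compared between days to ask whether it changes as cells approach day 0. A single region differed, and it is given here after its value was seen. At 5:126537894-126538699, over 10 kb from any gene, the log2 effect was -0.31 (SE 0.17) on day -2, 0.17 (SE 0.19) on day -1 and 0.96 (SE 0.20) on day 0. The difference of day 0 from day -2 was 1.26 (SE 0.26), an edgeR adjusted p of 0.046, higher. A peak inside the kinase gene Camk2d had 1.88 (SE 0.42, adjusted p = 0.082), chosen after its value was seen. For day -1 against day -2 and day 0 against day -1, edgeR called 0 of 13670 matched peaks, with 660 and 700 at an unadjusted p under 0.05, and no other tool was run. For day 0 against day -2 it called 1, with 881. That call was lost with matching by any overlap of 1 bp (adjusted p = 0.056), under total-count scaling, and without 12 of the 23 libraries left out singly, with an adjusted p of 0.0048 to 0.99961 over its alternatives. These were Kdm5c siRNA replicates 1, 2 and 4 and scramble replicates 2 and 3 of day -2, scramble replicate 4 of day -1, and Kdm5c siRNA replicates 1, 2 and 4 and scramble replicates 1, 3 and 4 of day 0. Without Kdm5c siRNA replicate 3 of day -2 there were 7 calls for this pair and 2 for day -1 against day -2. Leaving out scramble replicate 4 of day -2, 2 of day -1 or 2 of day 0 gave 2.

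Averaged over the 3 days, a fit added after the data were examined, the Gm10222 and Myo3a peaks fell by 0.55 each (SE 0.08 and 0.09, edgeR adjusted p = 1.4e-05 and 4.4e-05), and no other of the 13670 peaks passed, where 896 had an unadjusted p under 0.05. Without Kdm5c siRNA replicate 3 of day -1 there were 4 calls. Hnrnpu had -0.49 (SE 0.11), with an edgeR adjusted p of 0.094. Neither the Gm10222 nor the Myo3a call held under total-count scaling, where both effects were -0.12.

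Fold changes of different days were nearly uncorrelated. Across the 13670 matched peaks, which are not independent replicates, Pearson's r was 0.044 for days -1 and -2, -0.083 for days 0 and -2, and 0.075 for days 0 and -1, with Spearman's rho of 0.046, -0.071 and 0.065. Jackknife errors of r, leaving out libraries, were 0.048, 0.110 and 0.051. Over all tested peaks the median SE of a log2 fold change was 0.35, 0.28 and 0.32 on days -2, -1 and 0. Noise of this size pulls r toward 0, so a small effect shared by the days cannot be excluded. In the fit over matched peaks no peak was called on any single day, so none could be shared. In a comparison added after the data were examined, at an unadjusted p under 0.05, days -1 and -2 shared 28 lower peaks where independent lists give 13.2 (Fisher's exact p = 0.00017), and days 0 and -1 shared 32 higher ones against 14.2 (Fisher's exact p = 2.3e-05) and 19 lower ones against 11.1 (Fisher's exact p = 0.020). The other 3 overlaps were 6 against 7.18, 7 against 8.15 and 8 against 10.2. Peaks are not independent of each other, so these p-values are too small.

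Peak sets of the days overlapped in part. By 50% reciprocal overlap, 18957 peaks were shared by days -2 and -1, which is 22.6% of the first set and 59.3% of the second. Days -2 and 0 shared 18590, and days -1 and 0 shared 16989. Change of scramble libraries over time was not tested here.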

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

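The tests on shares of nuclear counts were chosen only after the results were seen. Of 74 groups of 4 libraries examined for a value far from the other 3, 2 had one, where chance gives about 1 in 20 groups. On day -1, Kdm5c siRNA replicate 4 had 24.053% of its nuclear counts in the 1000 most abundant nuclear peaks, against 26.0% to 26.2% in the others of its group. On day 0, scramble replicate 1 had 77.542 normalised counts at S100a10, against 102 to 105 in the other scramble libraries.

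The siRNA effect at 5:126537894-126538699 differed between day 0 and day -2 by 1.2646 on the log2 scale. Regrouping the libraries within days at random, 11 of 100 groupings called at least 1 peak for this pair of days, and the highest of the others called 31, so chance cannot be excluded. For day -1 against day -2 and day 0 against day -1 the real count was 0, which 100 of 100 groupings meet by construction, so these say nothing about chance. The highest others called 6 and 9.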

How the results depend on the processing

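Chosen after the results were seen were the tests without mitochondrial peaks, on promoter-class peaks only, on nuclear shares, on the mitochondrial share, on means over days, and on fry's mixed p, and leaving out libraries for camera's lists and for the correlation of effects between days. Counts of called peaks stayed within 1.5 times the reported one in 7 of 18, 16 of 18 and 3 of 17 alternatives on days -2, -1 and 0. They did so in 25 of 26 for day -1 against day -2, 8 of 26 for day 0 against day -2, 26 of 26 for day 0 against day -1 and 24 of 26 for the mean over days. With RLE size factors 1 and 2 peaks were called on days -2 and 0, against 2 and 1 as reported. Total-count scaling called 1224, 1 and 0 on the 3 days, 0 for day 0 against day -2, and 10229 for the mean over days against 2. By its construction, lower mitochondrial counts lift all nuclear peaks of a library. Why the number of calls differed so much between days was not tested. DESeq2 called 0 on days -2 and 0, abundance above the median 1 on day -2, no filter 6 on day 0, and an adjusted p under 0.01 left 1 and 0. Without mitochondrial peaks there were 1 and 2, and among promoter-class peaks, where neither called nuclear peak is tested, 0 and 0. Matching by any overlap of 1 bp left 0 for day 0 against day -2. With replicate number as a block there were 5, 1 and 0 calls on days -2, -1 and 0. Replicate numbers did not pair the libraries: same-numbered deviations correlated at -0.039 to 0.157, and not every library matched its own number best. With that block the Myo3a peak, at -0.66, was not called, and fry's mixed test on day 0 gave proliferation genes an adjusted p of 0.27 and cell cycle inhibitors 0.0048. It moved no other list count or difference between days past a threshold. Leaving out each library in turn gave 2 to 11 calls on day -2, 0 on day -1, 0 to 10 on day 0, 0 to 2 and 0 to 7 for days -1 and 0 against day -2, and 2 to 4 for the mean over days. Lists passing fry's mixed test were 0 to 1 on day -1 and 0 to 2 on day 0, while camera's 0 lists stayed 0 in 35 of 35 alternatives, including the 23 that left out a library. The mitochondrial difference ranged from -11.9 to -7.31, -3.17 to -1.50 and -6.12 to -2.14 percentage points, and that of the promoter-class share from -7.80 to -4.70, -1.70 to -0.816 and -3.23 to -1.08. On day 0, 2 libraries against 4 cannot give an exact p under 0.0667, nor 3 against 3 one under 0.10. The promoter-class difference turned positive among nuclear counts, at 0.152 and 0.769 on days -1 and 0. Within 1 kb of a coding gene's end it was 0.0225, 0.108 and 0.865, and within 2 kb 0.0617, 0.0999 and 0.904. The Kdm5c peak turned to 0.16 under total counts on day -2 and to -0.19 without Kdm5c siRNA replicate 2 on day -1, where leaving out 1 library gave -0.19 to 0.29. Of 227 alternatives for 15 single peaks, 202 kept direction and side, 16 lost a call, 7 gained one and 2 turned. The losses fell on the only called peaks among these. They were 4 of 15 alternatives for Gm10222 and 5 of 15 for mt-Tf on day -2, and 7 of 14 for Myo3a on day 0. Except where construction is named, the cause was not tested. GC correction, motifs and distances to transcription starts were not run. In simulated data at this depth and number of libraries, which were not varied, a 1.5-fold change was recovered in 4.5%, 8.5% and 8% of peaks on days -2, -1 and 0, and in 9%, 17% and 15% of those above the median count. The simulated spread was not set for each single peak, and libraries were drawn independently, so recovery in the real data may be lower.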

Other observations

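The tests on mitochondrial shares over the 3 days and on the 2 broad mitochondrial peaks, on fry's mixed p, on the mean effect over days, on the chromosome 10 stretch and on the spread of the adjustment for total counts were chosen only after the results were seen.

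The gene lists differed in how many members had a promoter-class peak with enough counts to be tested over both arms. On day -2, 30 of 33 proliferation genes, 15 of 18 cell cycle inhibitors and p53 targets, 23 of 30 histone H3 lysine 4 enzymes and partners and 20 of 26 adipogenic transcription factors had such a peak. Median normalised counts in scramble libraries were 77.5, 99.7, 81.0 and 85.2, where the median over all gene peaks was 65.2. Of 35 germline genes 15 had a peak and 8 a tested one, and of 19 myogenic genes 7 and 6, with medians of 16.2 and 16.3, or the 9.14th and 9.15th percentile of gene peaks. Tested members were 2 of 15 for epithelial genes, 3 of 15 for macrophage and blood cell genes, 5 of 14 for endothelial genes and 0 of 13 for thermogenic genes. Differences between lists were not tested. Pparg had 68.1 ± 3.67 counts in scramble libraries on day -2 and Cebpa 95.5 ± 16.2 (SD, n = 4 each).

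A stretch of chromosome 10 from 117277541 to 117792736, with limits chosen after the data were seen, stood far above the rest of the genome. It holds Lyz2, Cpsf6, Cpm, Mdm2, the ubiquitin ligase that targets p53, Slc35e3 and Nup107. Median count density per kb was 728, 594 and 780 on days -2, -1 and 0, against 64.7, 55.0 and 63.1 elsewhere. The flanking 500 kb had 60.6, 55.1 and 78.1. The Mdm2 peak was at the 99.97th percentile of gene peaks on each day, with 6168, 4934 and 6951 mean counts. The macrophage marker Lyz2 lies in the same stretch, at the 99.9th percentile on each day. Of 2250 windows of 500 kb, 4 others exceeded 2 times the median on all days. They start at 107000000 and 118500000 on chromosome 10 and at 77500000 and 78000000 on chromosome 2. Cwc22 lies in the window from 77500000.

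Extra copies of this stretch in the cell line are a candidate explanation. The 10th percentile of density inside was at least 6.6822 times the median outside on each day, but the limits were chosen for this density, so the value cannot tell extra copies from other sources. Its peaks had a mean log2 fold change of 0.16, -0.10 and -0.17, with 238 of 266 above 0 on day -2 and 155 of 178 below 0 on day 0. The stretch's share of nuclear counts was 3.91% and 3.63%, 3.73% and 3.87%, and 4.27% and 4.47% with Kdm5c siRNA and scramble, the smallest exact permutation p being 0.14286. An effect of the siRNA cannot be told apart from variation between libraries at this number of samples.

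The lower mitochondrial share with Kdm5c siRNA had an exact permutation p of 0.00040816 over the 3 days, which argues against chance assignment of libraries, although the measure was picked from these data. After adjustment for total counts at least 83.768% of the log2 difference stayed on days -2 and 0, at least 59.4% at the upper 95% limit of the slope, and at least 69.4% without any 1 library. This argues against library size as the whole cause, for which under 50% was to stay. The difference went from -0.65 (SE 0.22) to -0.55 (SE 0.19) on day -2, with an exact permutation p of 0.0286 before and after. On day 0 it went from -0.57 (SE 0.30) to -0.54 (SE 0.33), and the exact p from 0.0286 to 0.0571, since 1 more of the 35 assignments gave a difference as large. A part played by library size stays open. The fold changes of the 2 broad mitochondrial peaks lay within 0.02631 of each other on the log2 scale on these days, which both less mitochondrial DNA per cell and fewer mitochondria carried into the preparation of nuclei could give. These cannot be told apart here because the counts measure only their product, relative to nuclear counts in peaks. More nuclear counts in peaks would also lower the share, without any mitochondrial change. Mean nuclear counts in peaks were higher with Kdm5c siRNA on each day. Their exact permutation p-values were 0.543, 0.486 and 0.20 on days -2, -1 and 0. A part played by nuclear counts stays open, and an effect of the siRNA remains an open hypothesis.

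The nuclear peaks that fell may owe their change to reads from mitochondrial DNA. Over the 23 libraries, deviations from group means followed the log2 mitochondrial to nuclear ratio with r = 0.94976 (rho 0.953) for the Gm10222 peak and r = 0.8186 (rho 0.853) for the Myo3a peak, with permutation p-values of 1e-05 for both measures at Gm10222, and 0.00036 and 7e-05 at Myo3a. Without the 2 libraries farthest from the median, r was 0.932 and 0.778, against a 95th percentile of 0.427 over 13316 matched peaks. After removal of this slope the effects on days -2, -1 and 0 were -0.07, -0.11 and 0.03 at Gm10222 and 0.01, 0.04 and -0.06 at Myo3a. Before removal the exact permutation p was 0.0571, 0.0857 and 0.0571 at Gm10222 and 0.143, 0.229 and 0.0571 at Myo3a, none under 0.05. The exact permutation p of what remained was 0.486, 0.143 and 0.657 at Gm10222 and 0.971, 0.657 and 0.657 at Myo3a.

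For each count of calls above 0, other splits of the same libraries gave counts as large, and chance cannot be excluded for these counts. The splits compare only how many peaks or lists were called, not how small their p-values were. A real count of 0 is met by each split by construction and says nothing about chance. On day -2, 7 of 35 splits called at least the 2 peaks of the real one, and the highest other called 76. That split set Kdm5c siRNA replicates 1 and 2 with scramble replicates 1 and 4 against the rest, of that day. A count so far above the real one points to a possible structure of the samples, but it is the highest of 34 other splits and no such structure was tested. On day -1 the real count was 0, met by 35 of 35, and the highest other was 1. On day 0, 8 of 35 reached 1, and the highest called 23, with Kdm5c siRNA replicates 2 and 4 and scramble replicate 1 on one side. This count too is the highest of 34 other splits, and a structure of the samples was not tested. For the mean over days, 10 of 100 reached 2, with 4 at most. That comparison does not weigh the edgeR adjusted p of 1.4e-05 and 4.4e-05 at the Gm10222 and Myo3a peaks, so it cannot judge these peaks singly. For lists by camera the real count was 0 on each day, met by 35 of 35 splits, and the highest other was 1, 0 and 1. By fry's mixed test the real counts were 0, 0 and 1, reached by 35, 35 and 4 of 35 splits, and the highest other was 1, 2 and 1.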
